A study of Mus musculus with 6 samples.

How the data were processed

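Droplet-based 5' single-cell RNA sequencing had been done on live CD45+ cells sorted from the inguinal lymph nodes of mice immunised with NP-CGG, a hapten coupled to chicken gamma globulin. There were 6 libraries, 1 for each of 6 groups. The authors deposited, for every library, a table of raw UMI (unique molecular identifier) counts per Ensembl gene and cell barcode. The submitters' processing notes name bcl2fastq 2.20, Cell Ranger 6.0.0 and the mouse genome build mm10. The reads were not processed again. The tables held 32285 genes each, of which 32158 identifiers were matched to a symbol, and 60970 barcodes in all. The barcode with the fewest UMIs held 500, so a barcode filter had been applied before deposit, and which one is not stated. No cell annotation from the authors was used here.

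Barcodes with under 500 detected genes or over 10% mitochondrial UMIs were left out, which took away 282 barcodes. Doublets were called per library with Scrublet as implemented in scanpy 1.11.5, at an expected rate of 8%. It called between 3.36 and 4.42% of the barcodes of a library, and these were removed, leaving 58365 cells. Counts were scaled to 10000 UMIs per cell and logged. The 2000 genes with the highest mean dispersion rank over the libraries were taken, without immunoglobulin, T cell receptor, mitochondrial, ribosomal protein, haemoglobin and Y-linked genes and without Xist, Tsix, Commd3 and Commd8. Then 30 principal components, 20 nearest neighbours and Leiden clustering (igraph 0.11.9) at a resolution of 1.0 gave 20 clusters. No batch integration was applied, because each group is a single library. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

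Clusters were named from marker genes listed before the data were examined, together with the gene lists, the rule for naming genes, the comparisons and 28 alternative settings. The thresholds that turn the marker scores into names were set after the clusters were seen. B-like, CD4 T-like and CD8 T-like cells are called B cells, CD4 T cells and CD8 T cells here. A T cell cluster counted as CD8 when over 60% of its cells held a Cd8b1 UMI and as CD4 when under 20% did. The cluster of activated CD4 T cells, called Icos-high, was clustered again on 15 principal components, and its part with at least 3 follicular helper markers among its 10 leading genes was called Tfh-like. Ranked against all other cells, a few B and T cell clusters had 1 marker of another class and none of their own among their 10 leading genes. Ranked against the cells outside their lineage, every B and T cell cluster led with more of its own markers, and the shares without those clusters are among the alternatives. One cluster of shallow cells stayed unnamed and held between 0.184 and 0.561% of the cells of a library. A mixed T cell cluster, with between 0.248 and 0.472%, counted in no T cell class. Naive-type clusters are B, CD4 T or CD8 T clusters with at most 1 activation, effector or cycle list gene among their 10 leading genes. Germinal centre B-like, Icos-high, Tfh-like and regulatory T-like clusters are not among them.

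With 1 library per group there was no test, and no p-value, standard error or count of changed genes was made from cells. Shares of cells are given with exact Clopper-Pearson intervals and UMI sums with exact Poisson intervals, both at 95%. Ratios have exact conditional binomial intervals. All of these cover counting error only and say nothing of variation between animals or libraries. A count of 0 allows up to 3 counts. Gene ratios came from UMIs summed over the cells of a class in a library, divided by all UMIs of that sum, with 1 UMI added to each side, for genes with at least 100 UMIs over both libraries. The ratios of 28 fixed gene lists were described by their median and its percentile among 10000 random lists matched in 20 bins of expression. Such a percentile is a description of these libraries, since genes of 1 library are not independent replicates. A list is called outside the random range below the 2.5th or above the 97.5th percentile. Ribosomal protein and mitochondrially encoded genes were lists of their own.

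The genes to be named came from a fixed rule. In each of the 4 comparisons these were the 6 genes with the highest and the 6 with the lowest ratio in B cells, and the 4 highest and 4 lowest in CD4 and in CD8 T cells, among genes whose interval excluded an equal level. Immunoglobulin, T cell receptor, mitochondrial, ribosomal protein, haemoglobin, predicted and Y-linked genes, Xist and Tsix were left out of this ranking. Commd3, Commd8 and the measured members of 3 lists (germinal centre B, plasma cell and chemoattractant receptors) were part of it in every comparison. So were the 4 members with the largest ratio, in either direction, of any list outside the random range. The text gives only some of these genes, and which of them was decided after their values were seen. Gene positions came from the GENCODE annotation of mm10.

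The arithmetic was tested on simulated data, with sums drawn as Poisson counts, which the intervals assume as well. UMIs that come together from single cells were thus not simulated, and the intervals of genes with such UMIs are too narrow. In B cells, with 200 genes changed at random, the intervals of genes changed 1.5-fold excluded an equal level in 93.0 to 95.4% of cases over the 4 comparisons, and those of genes changed 2-fold or 4-fold in all cases. The share for 1.5-fold was 96.6 to 98.7% in CD4 T cells and 85.5 to 95.6% in CD8 T cells. In CD8 T cells genes changed 2-fold were found in at least 98.3% of cases. A pair of simulated comparisons with the same effects on every gene correlated with an r of 0.821, and a pair without any effect with -0.03. The real ratios in B cells had standard deviations of 0.24 for the deletion and 0.22 for celastrol in WT, less than the simulated effects. The r of 0.821 is thus no scale for the real correlations.

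Those 28 settings were other gene and mitochondrial filters, no doublet removal, other clustering resolutions, thinning to 1500 UMIs per cell, no cell cycle genes among the variable genes, UMI gates in place of clusters, other scalings and count minimums, naive-type clusters alone, 10 bins of expression, rank correlation, and cells instead of UMIs for the immunoglobulin classes. A further 5 were added after seeing the data: the UMI gates on thinned cells, germinal centre B-like cells without T cell receptor complex genes, clustering without the germinal centre and follicular helper markers, leaving out the clusters described above, and shares of all kept cells. Thinning left out 403, 308, 310, 150, 134 and 185 shallower cells in flox/+, flox/flox, WT vehicle, WT celastrol, C170A vehicle and C170A celastrol.

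Xist lay between 221 and 256 CPM in every library, and 4 Y-linked genes together had at most 2 UMIs, so all libraries had the pattern of female animals. Cells with at least 4 markers of macrophages, monocytes, neutrophils, conventional type 1 dendritic cells, erythroid cells, platelets, stroma or mast cells (plasmacytoid dendritic cell markers were not used, as B cells share them) numbered at most 2 for any of these types in any library, below the limit that a count of 0 allows.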

Results

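The series measured gene expression in single live CD45+ cells from the inguinal lymph nodes of C57BL/6 mice, 7 days after subcutaneous immunisation with 100 µg NP-CGG. It has 2 arms. In the first, CreERT2 mice carrying 1 floxed Commd3 copy (flox/+) or 2 (flox/flox) received tamoxifen on 3 consecutive days from 9 days before immunisation. In the second, wild-type (WT) mice and mice homozygous for the C170A form of COMMD3 received vehicle or celastrol, a plant triterpenoid, at 1 mg/kg 2 times a week from 7 days before immunisation. COMMD3 forms a complex with COMMD8 that promotes the chemoattractant-guided migration of lymphocytes, and C170A changes cysteine 170, the residue at which celastrol binds it. Each of the 6 groups is 1 library, so no value has a replicate and no difference between groups was tested. Intervals in brackets are 95% intervals that cover counting error only.

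The libraries held between 8486 and 11134 barcodes and, after filtering, between 8163 and 10649 cells. Kept cells had a median of 3070 UMIs in the Commd3 flox/+ library, 3088 in flox/flox, 3413 in WT vehicle, 3778 in WT celastrol, 4006 in C170A vehicle and 3824 in C170A celastrol. The C170A libraries were thus the deepest per cell, with medians of 1652 and 1601 genes against 1270 to 1447 in the others. B cells made up between 40.2 and 49.0% of the kept cells, CD4 T cells between 29.7 and 33.3% and CD8 T cells between 20.5 and 27.0%. The largest cluster of each class differed between the C170A libraries and the 4 other libraries. For B, CD4 T and CD8 T cells these were clusters 1, 3 and 4 in the C170A libraries and clusters 0, 2 and 5 in the 4 other libraries.

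The first comparison asked what loss of Commd3 does to the cells of the responding lymph node. Commd3 itself stood at 38.1 CPM (counts of UMIs scaled to an equal total per library) [36.1, 40.2] in the flox/+ library and 3.78 [3.14, 4.51] in flox/flox, so 9.98% of the heterozygous level was left (log2 ratio -3.32 [-3.61, -3.07]). The loss was seen in B cells (log2 ratio -3.64), CD4 T cells (-3.42) and CD8 T cells (-2.89). The heterozygous library in turn stood at 59.6% of the WT vehicle level of 64.0 [61.5, 66.6]. Commd8, which encodes the partner protein, was at 84.9 CPM in flox/+ and 81.8 in flox/flox (log2 ratio -0.05 [-0.13, 0.02]). Bmi1, a polycomb gene that begins 786 bases downstream of Commd3, had a log2 ratio of 0.06 [-0.14, 0.26]. Commd3 (ENSMUSG00000051154) lies on chromosome 2 of mm10 at 18672384 to 18676231 on the plus strand, and Commd8 (ENSMUSG00000029213) on chromosome 5 at 72156575 to 72168189 on the minus strand.

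**Figure D1:**
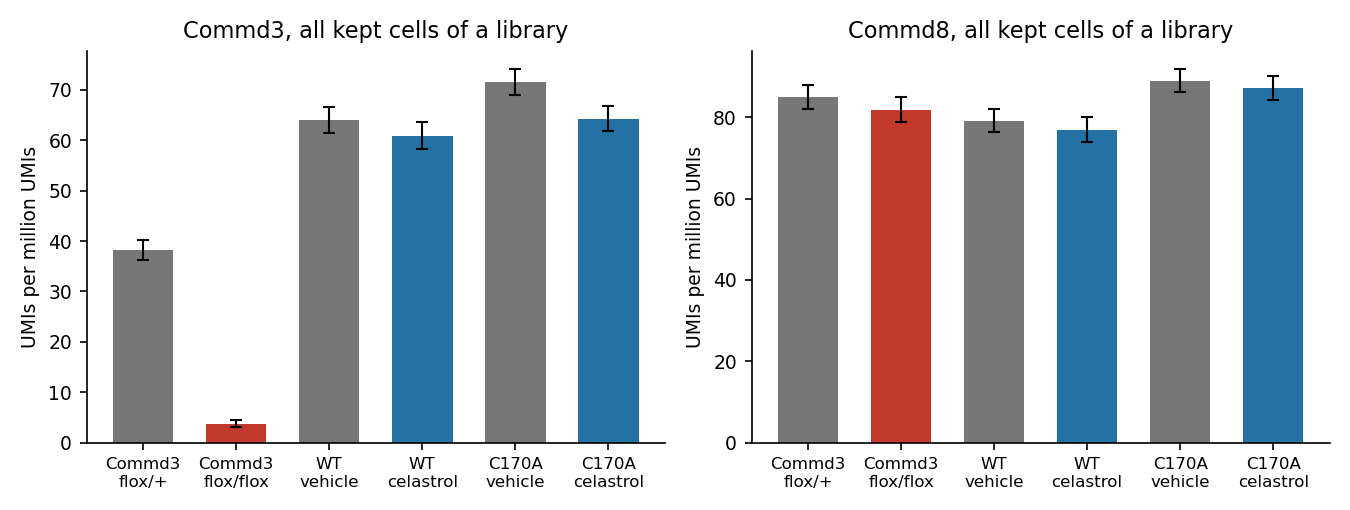
Levels of Commd3 (left) and Commd8 (right) in CPM over all kept cells of each of the 6 libraries, with bars for the level and lines for the exact 95% Poisson interval, which covers counting error only. Commd3 is at 3.78 in the flox/flox library and between 38.1 and 71.5 in the others, while Commd8 lies between 76.9 and 88.9 in all 6.

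Germinal centre B-like cells were 4.78-fold less frequent without Commd3. They made up 3.58% of B cells [3.05, 4.17] in flox/+ (158 of 4414 cells) and 0.749% [0.502, 1.07] in flox/flox (29 of 3872), a log2 ratio of -2.26 [-2.88, -1.68]. The 3 control libraries (flox/+, WT vehicle and C170A vehicle) lay between 3.26 and 3.92%. Counted by a gate of at least 2 germinal centre marker genes per cell instead of by cluster, the share was 4.55% in flox/+ and 3.04-fold lower in flox/flox, where 0.592 to 0.706% of T cells of the same libraries also passed that gate, at a higher median depth. Tfh-like cells, the follicular helper T cells that sustain germinal centres, numbered 17 of 3260 CD4 T cells in flox/+ and 6 of 3211 in flox/flox (log2 ratio -1.48 [-3.11, -0.07]). A gate on follicular helper markers instead gave 10.8 and 9.56% of CD4 T cells, but it also took 2.99 to 5.17% of B and CD8 T cells. Icos-high CD4 T cells as a whole made up 4.14 and 4.48% of CD4 T cells, regulatory T-like cells 6.23 and 6.82%, and B cells 41.4 and 40.2% of all cells, each with overlapping intervals. CD4 T cells were 30.6% of all cells in flox/+ and 33.3% in flox/flox (log2 ratio 0.12 [0.05, 0.19]), and CD8 T cells 27.0 and 25.3% (-0.09 [-0.17, -0.01]).

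**Figure D2:**
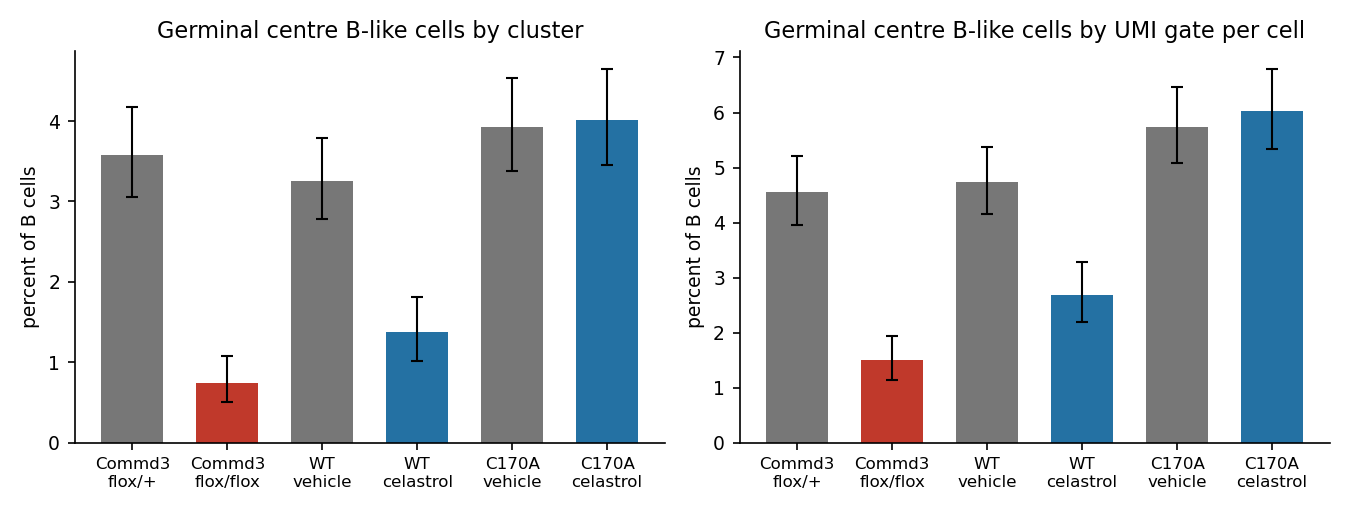
Share of B cells that are germinal centre B-like, in percent, by cluster (left) and by a gate of at least 2 marker genes per cell (right), for the 6 libraries, with exact 95% Clopper-Pearson intervals for counting error only. By cluster the flox/flox library is at 0.749% and the WT celastrol library at 1.37%, while the other 4 libraries lie between 3.26 and 4.02%.

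Within all B cells, every one of the 10 germinal centre genes was lower in flox/flox (median log2 ratio -1.77, below all 10000 random lists). They included S1pr2, which keeps B cells inside germinal centres (-1.97), Mybl1 (-2.76), Gcsam (-2.47) and Nuggc (-2.82). Bcl6, the master regulator of the germinal centre programme, differed least (-0.55 [-0.70, -0.40]). In naive-type B cell clusters alone, which leave out the germinal centre cells, the median of the list was -0.11. Cell division genes followed: 8 of 8 measured G2/M genes were lower (median -1.68), such as Mki67 (-2.27) and Birc5 (-1.83), and 12 of 12 S phase genes (median -0.22), a list that was inside the random range in naive-type clusters alone. For Ube2c (-3.35), 41.2% of the UMIs of the flox/+ library came from 1 cell. Jchain, which links IgM and IgA multimers, was lower as well (-2.29 [-2.53, -2.06]), and so was Ighg1, the IgG1 constant gene (-2.66). Both are among the 10 leading genes of the germinal centre B-like cluster, so these ratios are not separate from its smaller share. Xbp1 and Irf4, regulators of plasma cell formation, were at similar levels (0.11 [-0.00, 0.22] and -0.09 [-0.27, 0.09]).

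Chemoattractant receptor genes were slightly higher in B cells of the flox/flox library, in 8 of 10 measured members (median 0.11, percentile 99.4), but inside the random range in naive-type clusters alone. Ccr7, which guides cells to the T cell zone, had a log2 ratio of 0.24 [0.15, 0.33], Cxcr5, the receptor for the follicle, 0.21 [0.10, 0.32], S1pr1, the egress receptor, 0.18 [0.05, 0.30], and P2ry10 0.28. S1pr2, a germinal centre gene, was the main exception. In CD4 T cells 7 of 9 measured receptors were lower by small amounts (median -0.08, percentile 17.4), with Cxcr6 at -0.80 and Ccr7 at -0.07 [-0.13, -0.02]. The same list had a median of -0.01 in CD8 T cells, where Cxcr3, the receptor of effector cells, was higher (0.56) and Ccr9 lower (-0.43 [-0.58, -0.28]). The genes of the COMMD and retriever complexes, Commd3 among them, had a median of -0.04 in B cells, inside the random range.

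Interferon-stimulated genes went different ways in B and CD8 T cells after the deletion. In B cells 14 of 17 measured members were higher (median 0.19, percentile 100), led by Ifit3 (1.88), Ifit1 (1.78), Usp18 (0.91) and Isg15 (0.89), which encode antiviral or feedback proteins of the type I interferon response. Ifit3b, which is outside the list, was 4.45-fold higher (log2 ratio 2.16 [1.67, 2.72]). Ifit3b (ENSMUSG00000062488) lies on chromosome 19 at 34607970 to 34613401. In CD8 T cells all 17 were lower (median -0.24), Ifi27l2a most of all (-0.82 [-0.87, -0.76]), and in CD4 T cells 12 of 17 (median -0.12), with Ifi27l2a at -0.58 but Ifit3 at 0.38. The list of CD4 T cells was inside the random range in naive-type clusters alone and with genes of at least 30 UMIs. The immediate early gene Fos, which tissue handling can induce, was lower in B cells (-2.13), CD4 T cells (-1.22) and CD8 T cells (-2.68 [-3.37, -2.13]) of the flox/flox library, and the immediate early list was below the random range in B and CD4 T cells, and in naive-type clusters alone in B and CD8 T cells. In CD8 T cells 6 of 8 effector genes were higher (median 0.44, percentile 100), among them Ly6c2 (0.53), Tbx21, which encodes the transcription factor T-bet (0.53 [0.11, 0.95]), and Il2rb (0.48). Naive-type clusters alone leave out a cluster led by such genes, and there the list stayed above the random range. Glucocorticoid-responsive genes were higher in B cells (7 of 8, median 0.24), for example Fkbp5 (0.71) and Ddit4 (0.39). Dusp1, the member with the largest ratio in either direction, was lower there. The list was also above the random range in CD4 T cells (6 of 8 higher, median 0.11, percentile 99.4), but inside it in CD8 T cells (median -0.01).

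Other genes at the ends of the ranking were Mid1, a microtubule-associated ubiquitin ligase (1.97 in B, 1.12 in CD4 T and 1.32 in CD8 T cells), Cdk5rap1 (1.58 in B cells), which modifies mitochondrial tRNA, and Hist1h2ap (1.44 in B cells). Among CD4 T cell genes Fbxo17 (1.30), Plaur (1.24) and Ly6c2 (1.84, with 20.3% of its UMIs from 1 cell) were highest, and Ly6k (-1.53), Auts2 (-1.37) and Platr17 (-1.22) lowest after Commd3. In CD8 T cells Klra7 (1.08), Ildr1 (1.04) and Ifngas1 (0.98) were highest, and Chic1 (-1.65) and Ly6k (-1.58) were among the lowest. MHC class II genes, which B cells express strongly, were lower in CD4 T cells (median -0.32, percentile 0.01), for example H2-Aa (-0.67) and Cd74 (-0.46). Single cells supplied up to 20.8% of such UMIs there, and in naive-type clusters alone the list was inside the random range.

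The second comparison asked what celastrol does in WT mice. Germinal centre B-like cells were 2.37-fold less frequent after celastrol, at 1.37% of B cells [1.02, 1.81] (49 of 3565) against 3.26% [2.78, 3.79] with vehicle (161 of 4938), a log2 ratio of -1.25 [-1.74, -0.78]. The gate of marker genes gave 2.69 and 4.74%. B cells were 43.7% of all cells after celastrol and 49.0% with vehicle, and CD8 T cells 25.0% and 20.5%. The 3 control libraries lay between 41.4 and 49.0% for B cells and between 20.5 and 27.0% for CD8 T cells. WT vehicle stood at an end of each range, and both celastrol values lay inside. Tfh-like cells were 7 of 2490 and 12 of 2998 CD4 T cells, with overlapping intervals, and regulatory T-like cells were 7.15 and 7.24% of CD4 T cells. Commd3 itself stood at 60.9 CPM after celastrol and 64.0 with vehicle (log2 ratio -0.07 [-0.16, 0.01]), and Commd8 at 76.9 and 79.1.

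In B cells 9 of the 10 germinal centre genes were lower after celastrol (median -0.88, below all random lists), among them Eaf2 (-1.11), Gcsam (-1.09) and S1pr2 (-0.98), while Bcl6 stood at 0.05 [-0.07, 0.17]. In naive-type B cell clusters alone the median was -0.08. All 4 measured G2/M genes were lower (median -0.63), Ccnb2 at -0.87 and Mki67 at -0.82, as were 10 of 12 S phase genes (median -0.14), Uhrf1 at -0.86 and Mcm6 at -0.37, though the S phase list was inside the random range in naive-type clusters alone. Pclaf, a clamp-associated factor of dividing cells, was at -2.70, with 18.8% of its vehicle UMIs from 1 cell. Jchain, a leading gene of the germinal centre B-like cluster, was lower (-0.85 [-1.04, -0.67]), and Xbp1 (0.01) and Irf4 (0.08) were at similar levels. B cell activation genes were lower in 16 of 18 cases (median -0.11, percentile 0.390), including Nr4a1, an early gene of antigen receptor signalling (-0.87 [-1.11, -0.63]), and Cd83 (-0.41). In naive-type clusters alone, which leave out a cluster led by such genes, the list was inside the random range. The immediate early list, which tissue handling can raise and which shares Nr4a1, was lower too, in 8 of 10 members in B cells (median -0.11, percentile 1.21) and 8 of 10 in CD8 T cells (-0.13, percentile 0.900), but inside the random range in CD4 T cells and in naive-type clusters alone.

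Interferon-stimulated genes were lower after celastrol in all 3 classes of WT cells: in 15 of 16 in B cells (median -0.36), 17 of 17 in CD4 T cells (-0.27) and 15 of 17 in CD8 T cells (-0.14). Each class holds a cluster led by such genes. Ifit3 (-1.28 in B cells), Irf7, which amplifies interferon production (-0.67 in B cells), Ifit1 (-0.61 in CD4 and -0.63 in CD8 T cells) and Isg15 (-0.55 in CD4 T cells) were examples. Genes of the unfolded protein response were slightly higher in each class, in 12 of 14 members in B cells (median 0.07), 11 of 14 in CD4 T cells (0.12) and 11 of 14 in CD8 T cells (0.09). They included the chaperone genes Pdia4 (0.26 in B cells), Hsp90b1 (0.26 in CD4 T cells) and Calr (0.24 in CD4 T cells). Heat shock genes were inside the random range in B cells (median -0.04) and CD8 T cells (-0.01). In CD4 T cells they were slightly above it, with 8 of 11 members higher (median 0.04, percentile 99.1). Dnajb1 (-0.17) and Dnaja1 (-0.11) were among the lower ones there. Glucocorticoid-responsive genes were higher in CD4 T cells (7 of 8, median 0.18), as Ddit4 was (0.23).

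Receptors for migration went both ways in B cells, 5 of 10 higher and 5 lower. Cxcr5 (0.19 [0.08, 0.30]), S1pr1 (0.23), Ccr6 (0.17) and Ccr7 (0.12) were higher, and S1pr2, the germinal centre gene (-0.98), and Cxcr4 (-0.23 [-0.39, -0.07]) were lower. The list of chemoattractant receptors was inside the random range (percentile 94.2, and 43.4 with genes of at least 30 UMIs). Homing genes were higher in B cells in 10 of 17 cases (median 0.05, percentile 97.7), with Itga4 at 0.16, but inside the random range in naive-type clusters alone. In CD4 T cells genes of G protein signalling were lower in 10 of 14 cases (median -0.10, percentile 2.03), such as Gnai2 (-0.38 [-0.44, -0.32]), which encodes the G protein subunit that chemokine receptors use, Gnb1 (-0.52) and Grk2 (-0.23), a receptor kinase. This list too was inside the random range in naive-type clusters alone. NF-kB targets in B cells went both ways, 9 of 17 higher with a median of 0.11 above the random range, such as Ebi3 (0.58) higher and Bcl3 (-0.52) lower.

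At the ends of the ranking in B cells were Ly6k (1.37), Alox5ap (1.34), Cdk5rap1 (1.27), Uso1, a Golgi tethering factor (1.11 [0.96, 1.26]), Eps8l1 (-3.46 [-4.86, -2.60]), Slpi (-1.90), Tcf7 (-1.31) and Basp1 (-1.29). Lyz2, a myeloid gene, had a log2 ratio of 5.37, but 96.7% of its 181 UMIs came from 1 cell. Among CD4 T cell genes Nr4a3 (1.08) and Nrn1 (1.07) were high and Ybx3 (-1.45), Fndc10 (-1.09) and Map3k10 (-1.01) low. CD8 T cells had Cpt1a, the gate of mitochondrial fatty acid oxidation, at 0.82 and Vegfb at -1.01, and Egr3 (-0.93) and Nr4a1 (-1.07) low, with 18.8 and 22.6% of their vehicle UMIs from 1 cell.

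The third comparison repeated the celastrol treatment in C170A mice. The share of germinal centre B-like cells was close in both libraries: 4.02% of B cells [3.45, 4.64] after celastrol (175 of 4358) and 3.92% [3.38, 4.53] with vehicle (177 of 4512), a log2 ratio of 0.03 [-0.28, 0.34]. The difference between the log2 ratios of WT and C170A mice was -1.28, and it was not tested. B cells were 45.1 and 44.4% of all cells, and Tfh-like cells 19 of 2927 and 31 of 3132 CD4 T cells (log2 ratio -0.61 [-1.51, 0.26]). Regulatory T-like cells were 9.50% of CD4 T cells after celastrol and 8.01% with vehicle, with overlapping intervals. Commd3 stood at 64.2 CPM [61.8, 66.8] after celastrol and 71.5 [69.0, 74.0] with vehicle (log2 ratio -0.15 [-0.23, -0.08]), and Commd8 at 87.1 and 88.9.

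Heat shock genes were higher after celastrol in all 3 classes of C170A cells: 11 of 11 measured members in B cells (median 0.49), 11 of 11 in CD4 T cells (0.50) and 10 of 10 in CD8 T cells (0.46), each above all random lists. Hspa1b, an inducible HSP70 gene, had 9 UMIs in B cells with vehicle and 92 after celastrol (log2 ratio 3.33 [2.48, 4.64]). The co-chaperone genes Dnaja1 (0.99, 0.81 and 0.72 in B, CD4 T and CD8 T cells) and Dnajb1 (0.91, 0.92 and 0.95), and Hsph1, an HSP110 gene (0.86, 0.97 and 0.68), showed the size of the difference in abundant transcripts. In C170A over WT with vehicle the heat shock list had medians of -0.05, -0.01 and -0.07 in the 3 classes. Its percentiles were 4.86, 8.86 and 1.39, below the random range in CD8 T cells alone. A low C170A vehicle library could thus give part of the ratios after celastrol. Celastrol is known as an activator of heat shock factor 1. Hspa1b (ENSMUSG00000090877) lies on chromosome 17 at 34956436 to 34959238.

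**Figure D3:**
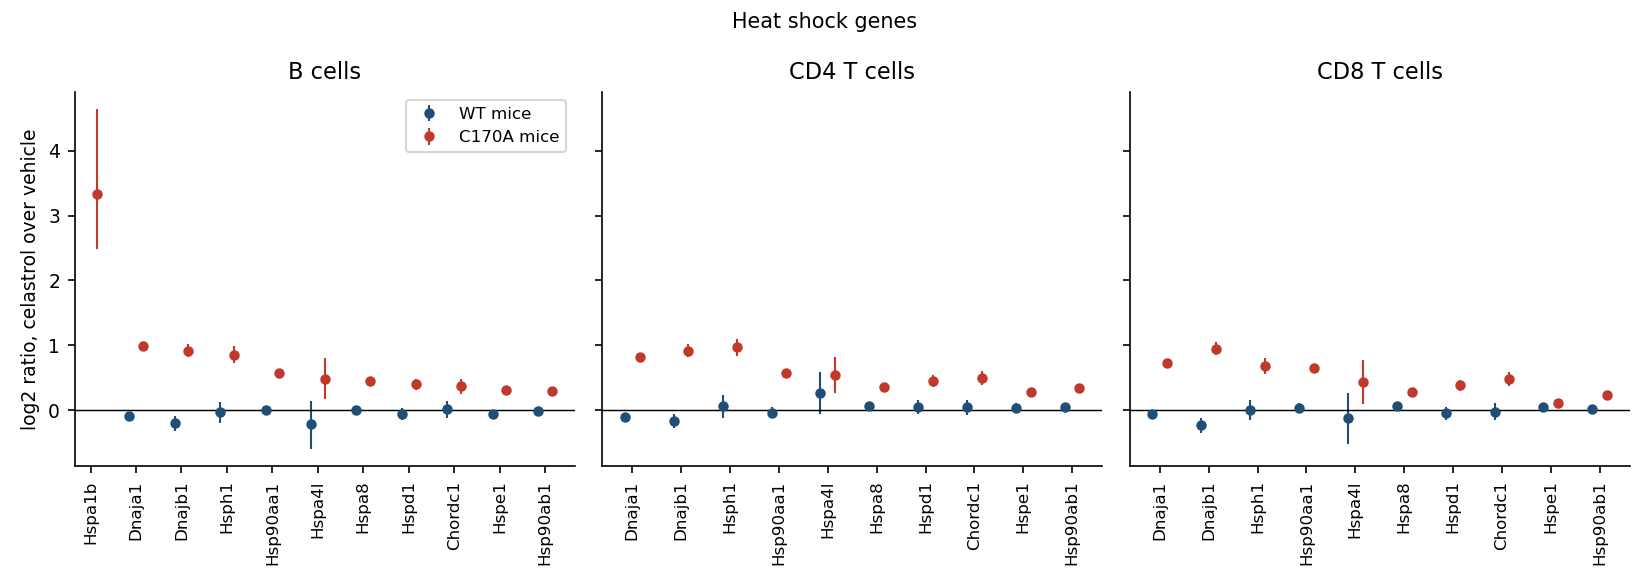
Log2 ratio of celastrol over vehicle (vertical axis) in B, CD4 T and CD8 T cells, for WT mice (blue) and C170A mice (red). Drawn are the heat shock genes measured in B cells of C170A mice, with 95% intervals for counting error only. Bag3, measured in CD4 T cells, is not drawn. In C170A cells every gene is above 0, Dnaja1 at 0.99 in B cells, and in WT cells most lie near 0; Hspa1b had enough UMIs for a ratio in C170A B cells alone.

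Interferon-stimulated genes were lower after celastrol in C170A mice, in 18 of 18 members in B cells (median -0.61), 19 of 19 in CD4 T cells (-0.41) and 17 of 18 in CD8 T cells (-0.34). Rsad2, which encodes the antiviral enzyme viperin (-1.50), Ifit3 (-1.27), Ifit2 (-1.17) and Ifit1 (-1.04) were examples from B cells, where Ifit3b, outside the list, was at -1.70, and Isg15 was at -0.64 in CD4 and -0.50 in CD8 T cells. Glucocorticoid-responsive genes were higher in 6 of 8 members in B cells (median 0.42), 7 of 8 in CD4 T cells (0.24) and 7 of 8 in CD8 T cells (0.38). They included Tsc22d3, which encodes GILZ (0.51, 0.61 and 0.71 in the 3 classes), Ddit4 (0.64, 0.61 and 0.55) and Cxcr4, the receptor of the dark zone and bone marrow niche (0.91, 1.51 and 0.78). In both lists the C170A vehicle library also differed from the WT vehicle library in the other direction, within the random range only for the glucocorticoid list of CD4 T cells, so a deviation of that library alone would give these signs. Of 10 measured chemoattractant receptors in B cells 6 were higher (percentile 74.9, inside the random range), among them S1pr2 (0.23 [-0.03, 0.49]), P2ry10 (0.17) and Ccr7 (0.12), while Cxcr5 (-0.14) and Gpr183 (-0.18) were lower. Of 13 receptors in CD4 T cells 9 were lower (median -0.12, below the random range), among them S1pr1 (-0.33) and Cxcr3 (-1.29), but the list was inside that range in naive-type clusters alone and with genes of at least 30 UMIs.

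The 10 germinal centre genes had a median of 0.12 in C170A B cells (8 higher, percentile 99.2), with Bcl6 at 0.16 [0.06, 0.27], but in naive-type clusters alone it was -0.08. Of 10 measured G2/M genes 8 were higher (median 0.40), Ccnb1 at 1.00 and Tpx2 at 0.91, with 10.4 and 10.7% of their UMIs from 1 cell. B cell activation genes were lower in 14 of 18 cases (median -0.11), Nr4a1 at -0.47 and Myc, a driver of growth, at -0.39 [-0.53, -0.25]. Genes of oxidative phosphorylation were lower in 18 of 19 cases in CD4 T cells (median -0.07) and in CD8 T cells (-0.11). Mitochondrially encoded genes were lower in all 3 classes, with medians of -0.07, -0.10 and -0.09, for example mt-Nd2 (-0.18, -0.23 and -0.19) and mt-Atp8 (-0.24, -0.22 and -0.27). The genes with the lowest ratios also included Cdk5rap1 (-1.33 in B and -1.39 in CD4 T cells), Xlr3b (-1.14 in CD4 and -1.51 in CD8 T cells), Ly6c2 (-1.25 in B cells), Ly6c1 (-1.40 in CD8 T cells) and Nsdhl, an enzyme of cholesterol synthesis (-0.93 in CD8 T cells). Ly6k (1.84 in B, 1.00 in CD4 T cells) and Ccna2 (1.02 in B cells) were high, as was Tnfsf9 in CD4 T cells (1.17). Ccl5 in CD4 T cells (1.41) took 38.2% of its UMIs from 1 cell, and without doublet removal it stood at -0.25.

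Across genes, the effect of the deletion and of celastrol in WT mice correlated weakly in B cells (Pearson r = 0.108 over 9017 genes), and not in the same direction in CD4 T cells (-0.064) and CD8 T cells (-0.072). As a rank correlation the value in B cells was -0.0097. For the deletion and celastrol in C170A mice r was -0.049, 0.099 and 0.072 in the 3 classes, and for celastrol in both genotypes -0.054, -0.045 and -0.077. These 9 correlations are across genes, which are not independent replicates. Among germinal centre B-like cells the share of heavy chain UMIs from Ighg1 was 52.3% [49.4, 55.2] in flox/+ and 42.7% [35.5, 50.2] in flox/flox, 42.0% [39.3, 44.6] in WT vehicle and 47.4% [42.1, 52.8] in WT celastrol, and 41.9% [39.4, 44.4] in C170A vehicle and 34.8% [32.4, 37.3] in C170A celastrol. UMIs of the same cell are not independent draws, so these intervals are too narrow. Counted as cells by their most abundant heavy chain, Ighg1 led in 63.4% [55.2, 71.0] in flox/+ and 53.6% [33.9, 72.5] in flox/flox. These shares were 49.7% [41.7, 57.7] in WT vehicle and 63.8% [48.5, 77.3] in WT celastrol. In C170A they were 49.7% [42.1, 57.3] with vehicle and 42.0% [34.5, 49.7] with celastrol. The intervals by cell overlapped in each comparison. Ighm, the IgM gene, held between 36.4 and 52.0% of heavy chain UMIs in all libraries. Cells of the plasma cell gate (at least 3 plasma cell genes and 10 Jchain UMIs) numbered 16, 4, 14, 8, 38 and 28 in flox/+, flox/flox, WT vehicle, WT celastrol, C170A vehicle and C170A celastrol. Each of them was also germinal centre B-like, and outside that class 0 cells passed. The upper end of the exact interval there was at most 0.0452% of the cells of a library, in WT celastrol.

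The fourth comparison set the C170A vehicle library against the WT vehicle library. The median of all genes was 0.10 in B cells, 0.12 in CD4 T cells and 0.11 in CD8 T cells, so ratios here are relative to a shift of that size. The largest difference was in interferon-stimulated genes, which were higher in C170A cells in 18 of 18 members in B cells (median 1.91), 19 of 19 in CD4 T cells (1.26) and 18 of 18 in CD8 T cells (1.15). Interferon-stimulated genes also led 1 cluster of each class, clusters 9, 10 and 13, which count as naive-type, so naive-type clusters alone do not leave these cells out. In B cells Ifit3b (log2 ratio 3.58 [3.14, 4.13]), Rsad2 (3.52), Ifit3 (3.30), Ifit1 (3.21), Ifitm3, a viral entry inhibitor (2.90), and Usp18 (2.87) led the ranking. Germinal centre B-like cells were 3.92 and 3.26% of B cells (log2 ratio 0.27 [-0.05, 0.58]). Tfh-like cells were 0.990% of CD4 T cells [0.673, 1.40] in C170A and 0.400% [0.207, 0.698] in WT (log2 ratio 1.31 [0.30, 2.40]). By the gate they were 15.9 and 10.3%, but the same gate took 7.58 and 5.18% of B cells and was higher in CD8 T cells as well, so it does not tell follicular helper cells apart. With cells thinned to an equal depth the gate took 4.24 and 3.11% of CD4 T cells (log2 ratio 0.45). CD8 T cells were 23.9 and 20.5% of all cells and B cells 44.4 and 49.0%. Commd3 stood at 71.5 against 64.0 CPM (log2 ratio 0.16 [0.08, 0.24]), and Commd8 had a log2 ratio of 0.17, both close to the shift of all genes.

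**Figure D4:**
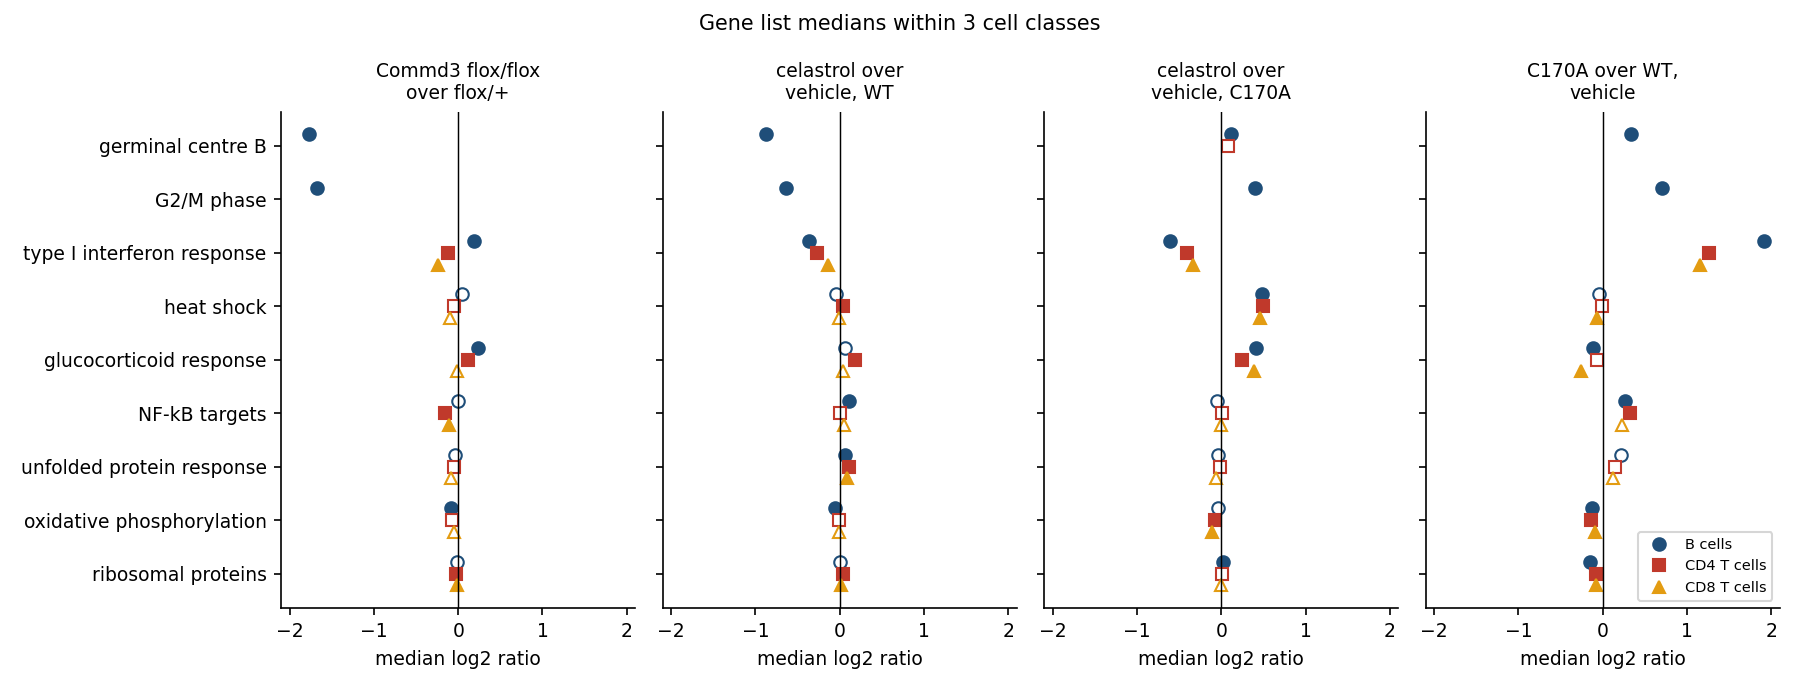
Median log2 ratio of 9 fixed gene lists (horizontal axis) in B cells (circles), CD4 T cells (squares) and CD8 T cells (triangles) for the 4 comparisons. Filled symbols lie outside the central 95% of 10000 random lists, and lists with under 3 measured genes are not drawn. The interferon list has the highest median, 1.91 in B cells of C170A over WT, and the germinal centre list the lowest, -1.77 after the deletion.

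All 10 germinal centre genes were higher in C170A B cells (median 0.33), Nuggc at 0.66 and Mybl1 at 0.62, and in naive-type clusters alone the median was 0.08, below the shift of all genes in B cells. Of 9 G2/M genes 8 were higher (median 0.71), for example Ccnb2 (0.78) and Birc5 (0.87). NF-kB targets were higher in 14 of 17 cases in B cells (median 0.26) and 14 of 16 in CD4 T cells (0.32), with the family members Nfkb2 at 0.66 and 0.63 and Relb at 0.46 and 0.71. In naive-type clusters alone the list of CD4 T cells was inside the random range. All 8 effector genes were higher in CD8 T cells (median 0.42), with Tbx21 at 1.29 [0.88, 1.74], Ly6c2 at 0.77 and Eomes at 0.62. Genes of G protein signalling were higher in CD8 T cells in 12 of 13 cases (median 0.32), Grk2 at 1.25 [1.13, 1.37], Gnb1 at 0.88 and Gnai2 at 0.83. Cxcr4 was lower (-0.96, -1.39 and -0.65 in B, CD4 T and CD8 T cells), as were Tsc22d3 (-0.58 in B and -0.69 in CD8 T cells) and Ddit4 (-0.62 and -0.33). Cxcr5 was higher (0.39 [0.29, 0.48] in B cells, and from few UMIs 1.28 in CD4 T and 1.11 in CD8 T cells). Ribosomal protein genes (medians -0.15, -0.08 and -0.08) and oxidative phosphorylation genes (-0.13, -0.14 and -0.10) were lower in the 3 classes. The ranking in T cells also held Eid2 (3.29 in CD4 and 2.68 in CD8 T cells), Xlr3b (3.16) and Sap30l (2.44) in CD8 T cells, and Ccnb1ip1 was low in every class (-1.95, -1.90 and -1.82).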

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

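The depth and doublet tests of the germinal centre pattern, the batch test and the isolation stress test were chosen only after the results were seen, and the depth test of the interferon genes and the test for a small share of stressed cells before. Celastrol in WT and C170A mice was compared over 64 pairs of list and cell class and 87 pairs of named gene and cell class. Opposite directions, each beyond its random range or interval, were found in 4 and 8 of these pairs. Cdk5rap1 counts in B and in CD4 T cells. Part of the 87 had been named for extreme ratios in these same comparisons. None of these differences was tested, because each group is 1 library.

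In B cells the germinal centre list had a median of -0.88 in WT and 0.12 in C170A mice, a difference of -0.998, and the G2/M list -0.63 and 0.40, a difference of -1.04. The G2/M medians are over different genes, 4 in WT and 10 in C170A mice, and of the 4 measured in both Aurkb was lower in both (-0.38 and -0.39). Mitochondrially encoded genes stood at 0.09 and -0.07 in B cells (difference 0.16), with mt-Nd2, a subunit of complex I, at 0.16 and -0.18 (0.34). Cxcr4 in B cells was at -0.23 and 0.91 (-1.14) and Cxcr5 at 0.19 and -0.14 (0.33), receptors that draw B cells to the dark zone and to the follicle. In CD4 T cells the co-chaperone genes Dnajb1 (-0.17 and 0.92, difference -1.09) and Dnaja1 (-0.11 and 0.81, difference -0.92) differed. The heat shock list as a whole was above the random range there in both genotypes (medians 0.04 and 0.50, percentiles 99.1 and 100). Cdk5rap1 was at 1.27 and -1.33 in B cells (2.60) and at 1.17 and -1.39 in CD4 T cells (2.56). The MHC class II list in CD8 T cells was at -0.20 and 0.31 (-0.51), with Cd74 at -0.49 and 0.31 (-0.80), genes that B cells express strongly. With genes of at least 30 UMIs the list was inside its random range in WT cells. In C170A over WT with vehicle it was at -0.27 (percentile 0.145). A low C170A vehicle library alone would thus give the sign seen in C170A mice.

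Sequencing depth and doublets of B and T cells can both alter the share of germinal centre B-like cells. B cells had a median of 2541 UMIs in flox/flox and 2494 in flox/+, and 3009 in WT celastrol and 2876 in WT vehicle. The libraries with the lower share were thus slightly deeper, which already ran against a loss of marker genes through low depth. With cells thinned to an equal depth, the log2 ratio of the gated share was -2.06 [-2.72, -1.46] for the deletion and -0.78 [-1.27, -0.30] for celastrol in WT, and the higher upper end of these intervals was -0.30. Without cells holding T cell receptor complex genes the ratios were -2.19 and -1.23, and the higher upper end was -0.76. Neither explanation accounts for the pattern. Variation between animals stays open, as each library stands alone.

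The higher interferon genes in the C170A vehicle library might reflect its greater depth, but among B cells with 1500 to 3000 UMIs (1580 in C170A and 2542 in WT) the median of 17 genes was still 1.87. A batch effect of the library could not be told apart. Leaving the interferon genes out, the ratios of C170A over WT in B and CD8 T cells correlated with an r of 0.771 over 8381 genes, where the 3 other comparisons gave 0.296 to 0.318. Such a shared shift would arise from the genotype, the animal or the library alike.

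The higher heat shock genes after celastrol in C170A mice might come from stress while cells were isolated. The immediate early list, which such stress raises, was at percentiles of 77.8 in B, 99.9 in CD4 T and 92.0 in CD8 T cells, above the random range in CD4 T cells alone. In naive-type clusters alone the immediate early list fell to a percentile of 6.10 in B cells and was inside the random range in all 3 classes, while the heat shock list stayed above all random lists. Naive-type clusters leave out those led by activation genes, and the activation list shares Nr4a1 and Egr1 with the immediate early list. The fall there can thus follow from the choice of clusters. Over all B cells the members went both ways (5 of 10 higher). These values cannot tell the explanations apart, and stress stays open. A small share of stressed cells does not account for it: without the 5% of cells highest in these genes in each library, the medians were 0.49, 0.47 and 0.47 in B, CD4 T and CD8 T cells.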

How the results depend on the processing

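The alternatives were set beforehand except for 5, which were chosen only after the results were seen. No paired analysis was possible because each group is 1 library from different animals. The lower share of germinal centre B-like cells held its direction in all settings, with log2 ratios between -2.42 and -1.60 for the deletion, the weakest by UMI gates, and between -1.41 and -0.78 for celastrol in WT. In C170A mice celastrol stayed between -0.00 and 0.10. Tfh-like cells were less stable: -1.84 to -0.17 for the deletion, -0.99 to 0.27 for celastrol in WT, -0.89 to -0.10 for celastrol in C170A and 0.45 to 1.75 for C170A over WT, the lowest by gates on thinned cells. Leaving cell cycle genes out moved nothing, since 0 of them were among the variable genes.

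Naive-type clusters alone, which leave out germinal centre cells, moved most. The germinal centre list in B cells stood at -0.113 for the deletion, -0.0783 for celastrol in WT, -0.0792 for celastrol in C170A and 0.075 for C170A over WT. After the deletion the S phase list in B cells was 0.0669 and Hells 0.24. In B cells Mzb1 was 0.0082 and the heat shock list 0.0094 for celastrol in WT, and Mef2b was -0.075 for C170A over WT. In CD4 T cells of C170A mice H2-Ab1 was 0.0091, H2-Aa 0.32 and Cd74 0.36 after celastrol, and the Tfh programme list was -0.0115 for C170A over WT. The cause of these moves was not tested. Of 86 combinations of list, cell class and comparison outside the random range, 58 stayed outside on the same side. MHC class II genes in CD4 T cells, for celastrol in C170A, turned to the other side. Lists that came to lie inside the range included, in B cells, the germinal centre list of every comparison, S phase and chemoattractant receptors for the deletion, and B cell activation, S phase and homing for celastrol in WT. In CD4 T cells they included interferon, NF-kB, MHC class II and immediate early genes for the deletion, G protein signalling for celastrol in WT, immediate early genes and chemoattractant receptors for celastrol in C170A, and NF-kB targets for C170A over WT. T cell effector genes for celastrol in WT were among them in CD8 T cells.

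Scaling by median of ratios gave the MHC class II list -0.0155 in B cells and the COMMD and retriever list -0.0143 in CD4 and -0.0146 in CD8 T cells for C170A over WT, and the interferon list -0.10 in CD8 T cells for celastrol in WT. This scaling adds 1 constant to all genes of a class: -0.1048, -0.1171 and -0.114 in B, CD4 T and CD8 T cells for C170A over WT, and 0.0327 in CD8 T cells for celastrol in WT. Without doublet removal Ccl5 in CD4 T cells was -0.25 for celastrol in C170A. In B cells the correlation of the deletion with celastrol in WT was 0.0402 for genes with at least 500 UMIs and -0.0097 by ranks, and with celastrol in C170A it was 0.021 and 0.0319. The cause of the moves of Ccl5 and of the correlations was not tested. Not all list members were measured: of 16 G2/M genes, 4 reached 100 UMIs in B cells for celastrol in WT.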

Other observations

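Each gene here was chosen only after its values were seen, and no test was run. Bmi1, a polycomb gene of self-renewal whose start lies 786 bases past the end of Commd3, was higher in the C170A libraries. It stood at 21.3 CPM with vehicle and 22.1 with celastrol, where WT mice had 13.8 and 12.3 and the flox/+ and flox/flox libraries 11.8 and 12.3. The log2 ratio of C170A over WT with vehicle was 0.63 [0.47, 0.78] over all cells, 0.52 in B cells, 0.96 in CD4 T cells and 0.56 in CD8 T cells. All genes of this comparison had medians of 0.10, 0.12 and 0.11 in those classes, with standard deviations of 0.35, 0.35 and 0.32. Genotype, animal and library cannot be told apart for this difference. Celastrol itself had a log2 ratio for Bmi1 of 0.05 [-0.08, 0.19] in C170A mice.

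Cxcr4, Tsc22d3 and Ddit4, which glucocorticoids induce, had opposite signs in 2 comparisons that share the C170A vehicle library, so a deviation of that library alone would give the same signs. In CD4 T cells Cxcr4 was at -1.39 in C170A over WT and at 1.51 after celastrol in C170A mice, Tsc22d3 at -0.69 and 0.61, and Ddit4 at -0.43 and 0.61. After celastrol in WT mice the same genes were at 0.07, 0.13 and 0.23 in CD4 T cells.

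Some genes differed alike in B, CD4 T and CD8 T cells. Sap30l, a subunit of a histone deacetylase complex, was higher in C170A over WT (2.63, 2.59 and 2.44), and Xlr3b, an imprinted X-linked gene, too (2.34, 2.33 and 3.16), while Ccnb1ip1, a factor of meiotic crossing over, was lower (-1.95, -1.90 and -1.82). Cdk5rap1 was higher after the deletion (1.58, 1.03 and 0.82), after celastrol in WT (1.27, 1.17 and 1.28) and in C170A over WT (1.21, 1.00 and 0.75), and lower after celastrol in C170A mice (-1.33, -1.39 and -0.90). Ly6k was lower after the deletion (-1.31, -1.53 and -1.58) and higher after celastrol in WT (1.37, 1.10 and 1.19). The 3 comparisons of the WT and C170A arm share vehicle libraries, so these signs can follow from single libraries.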
